A study of Caenorhabditis elegans with 6 samples.

How the data were processed

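The series holds 6 libraries from C. elegans strain TJ356 at the L4 to young adult stage: 2 from anti-GFP ChIP, 2 from anti-RNA polymerase II ChIP and 2 from Input DNA. Per the labels, worms were grown at 20 degrees in liquid culture and fixed in 2% formaldehyde for 30 minutes, and chromatin was sheared to 200 to 800 bp before precipitation and Illumina sequencing. Groups and replicate numbers were taken from the sample titles. The labels do not say that the libraries of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical. No library from a strain without the fusion protein, and no precipitation with a non-specific antibody, was among the samples analysed here.

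The authors deposited, for each library, 1 line per read from the aligner ELAND, whose version is not given in the sources used here, as the notes deposited with the files describe. These deposited files hold positions and match numbers (other values, not normalised): the matched position of each read and how many places in the genome it matched with 0, 1 or 2 errors. Reads of 35 bases (GFP ChIP 1 and Input 1, from one flow cell) and of 27 bases (the other 4 libraries, from another) were all matched by their first 27 bases. For the 4 ChIP libraries the authors also deposited lists of peaks called with PeakSeq in each library alone, per the deposited notes. In these lists the ChIP tags per region are whole counts as the authors gave them. The normalised Input tags and the excess over them are scores that the authors scaled and rounded. The enrichment is the authors' ratio of ChIP tags to normalised Input tags, and the p-value is a binomial p that the authors corrected to a q-value and listed up to 0.05. Which Input library the authors used for each list, and the genome build, are not given in the sources used here.

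Reads that matched a single position, nuclear or mitochondrial, made up 29.3% and 23.2% of all reads in GFP ChIP, 15.5% and 29.0% in Pol II ChIP and 19.2% and 26.1% in Input, and the nuclear ones among them were kept; between 58.1% and 77.3% of the reads in each library had no match. Reads at a position and strand already seen made up 21.9% and 13.1% in GFP ChIP, 14.6% and 9.00% in Pol II ChIP and 4.48% and 6.23% in Input, and were kept in the main results. Each read was moved 100 bp towards the centre of its fragment and counted in 500 bp windows. Libraries were scaled by TMM factors computed on 10 kb bins, which lay between 0.863 and 1.15. Median depth per tested window was 7 reads in Input 1 and 3 in Input 2, which limits every comparison with Input. Of uniquely matching reads, 49.7% and 86.6% had 0 errors in GFP ChIP, 83.3% and 80.5% in Pol II ChIP and 34.8% and 88.4% in Input. The low values are those of the first flow cell, and their effect on the results was not tested. Intervals and floors cover counting error only, since the reads carry no molecular identifiers, and do not allow for the choice of windows by their fold. A group with 0 reads was compared through a floor of 3 reads over the group.

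No reference genome was used. The sequence of the authors' build was rebuilt from the uniquely matching reads, which gave 67.9% of the 100265567 nuclear bases. Genes were placed on it through 88 mature microRNA sequences and 46 protein sequences (of C. elegans or human) written down from general knowledge; 74 microRNAs matched exactly at a single place, and the 46 proteins matched with tblastn from BLAST+ 2.17.0, at 40.6% identity or more. These 46 are what was kept: sequences for ctl-2 and hsp-16.1 were also tried and were left out after their matches could not be told from near-identical neighbours, and the queries now called eef-1A.1, hsp-90, rps-15A, rpl-8, rpl-10L and mir-58.1 were renamed to the symbols of the gene table after their matches had been seen. Each placement was required to lie on the chromosome, and in the order, that the gene has in the WBcel235 gene table, from which names and order alone were used; all 120 placed genes met this, though for the renamed and removed queries this check was not independent. Neighbouring microRNAs were joined, which left 108 loci, 62 microRNA and 46 protein-coding, of which 97 had a located start. These loci were chosen by what could be placed, on sequence rebuilt from ChIP and Input reads alike, and are not a random sample of genes. A start is the first matched base, not an annotated transcription start, and a gene span is the match plus 250 bp on each side, in place of the annotated gene bodies named in the plan. The hsp-12.6 and rol-6 genes, which the plan named, were not placed and are not analysed here, and no member could be placed of the lists of genes that fall with DAF-16 activity, dauer, histone, collagen, vitellogenin, germline, major sperm protein, chemoreceptor, Hox and tRNA genes.

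Windows with at least 20 reads over the 6 libraries (147829 of 200533), the upstream regions and the gene spans were tested with the quasi-likelihood F-test of edgeR 4.0.16 in R 4.3.3, two-sided, all 6 libraries in 1 fit with antibody as the only term, with Benjamini-Hochberg adjustment and a threshold of 0.05. The standard error of a log2 fold change was taken as its size divided by the square root of F and is approximate. Gene lists fixed in advance were tested with camera from limma 3.58.1 on log2 CPM, with a preset correlation of 0.01 and with an estimated one, where at least 3 members were located. Peak lists were compared by overlap of at least 1 bp against 100 circular shifts of 1 list along its chromosomes. The motif test used peak centres and flanks with at least 90% of bases rebuilt, a limit set after the files were seen. Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1 and pandas 2.3.3 was used for the rest.

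The groups share replicate numbers. The label of the Input libraries describes them as DNA of the same preparation as the precipitated chromatin, so the numbers were treated as pairs; for Pol II ChIP this is not stated outright. Deviations of same-numbered libraries from their group means correlated at 0.252 for GFP ChIP and Input, −0.00437 for GFP ChIP and Pol II ChIP and 0.00928 for Pol II ChIP and Input, and these values had been seen when the pairing was decided. The number 1 and number 2 pairs of GFP ChIP and Input are also the flow cells, whereas both Pol II ChIP libraries came from the second flow cell. A fit with the replicate number as a block and, added after the data were seen, a fit with the flow cell as a block stand beside the results they move.

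Genes and regions were named by a rule set before the data were examined: per gene comparison the 10 largest called changes in each direction with the same sign in both pairs, protein-coding genes and microRNAs apart, up to 4 members of each list with the largest and smallest changes, and sod-3, mtl-1 and daf-16; per peak comparison the 10 shared peaks with the best product of ranks; per window comparison the 10 runs with the largest mean fold. Outside this rule, ftn-1, hsp-16.2, let-7 and lin-4 in the GFP ChIP upstream regions, akt-1 in the Pol II ChIP spans, rpl-3 in the direct comparison and the longest runs of windows were chosen after their values were seen. Other settings tried were scaling by total reads and by DESeq2 size factors, 1 read per position and strand, no filter on low counts, a required fold of 2, the Wald test of DESeq2 1.42.0, limma with a trend, 1 kb windows, reads without the shift, shorter regions, a block, leaving out each library, stricter or other peak sets, and other overlaps and motif settings.

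The tests were tried on simulated counts with known changes. Of windows made 2, 4 and 8 times higher, 0%, 12% and 56% were recovered, and 8% of those made 4 times lower, so a window without a call says little at this depth. Of upstream regions made 2 and 4 times higher 10% and 90% were recovered, and of gene spans 10% and 50%. Of the calls, 2.56% were false for windows (1 call), 0% for upstream regions and 14.3% for gene spans (1 call), the last above the 5% aimed at. All 6 libraries were simulated from 1 mean profile with 1 dispersion. Differences between libraries, such as the opposite trends of the Input libraries with GC content, were left out, so these shares may not hold for the real data. Peak overlaps made at 0%, 50% and 90% were found as 5.88%, 52.6% and 90.7%, and motifs planted in 0%, 2%, 5% and 10% of peaks as 0.870%, 2.75%, 5.60% and 10.5%.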

Results

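Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map the binding of DAF-16, the FOXO transcription factor at the end of the C. elegans insulin/IGF-1 signalling pathway, in animals at the L4 to young adult stage. The strain, TJ356, carries a transgene that makes DAF-16 fused to green fluorescent protein (GFP), and the series describes the fusion protein as strongly overexpressed at this stage. DNA was taken from 3 kinds of library, 2 of each: an anti-GFP precipitation (GFP ChIP), an anti-RNA polymerase II precipitation (Pol II ChIP) and sheared DNA that was not precipitated (Input). Each library held between 2251806 and 10658626 reads. The reads that matched a single nuclear position numbered 3114487 and 1478716 for GFP ChIP, 1240681 and 1000751 for Pol II ChIP and 1306546 and 578243 for Input. Across 500 bp windows the GFP ChIP libraries correlated with each other at r = 0.774, the Pol II ChIP libraries at r = 0.615 and the Input libraries at r = 0.0243. GFP ChIP 1 and Input 1 came from one flow cell and the other 4 libraries from another. Positions are those of the deposited files, whose genome build is not given in the sources used here. Enrichments are log2 fold changes ± standard error with 2 libraries per group, and adjusted p-values are from edgeR.

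The comparison of GFP ChIP with Input asks where the anti-GFP precipitation was enriched. Without a strain that lacks the fusion protein or a non-specific antibody, DAF-16 binding cannot be told from non-specific recovery of DNA. The comparison was made first at 97 genes and microRNA loci whose start could be located by sequence. Of these upstream regions, from 1 kb upstream to 200 bp downstream of the matched start, 40 were higher in GFP ChIP and 1 was lower. Upstream of sod-3, which encodes a mitochondrial manganese superoxide dismutase and is a textbook DAF-16 target, GFP ChIP was higher by 2.17 ± 0.47 (adjusted p = 0.00284), from 186 and 83 reads against 18 and 10 in Input and 11 and 8 in Pol II ChIP. The upstream region of the related gene sod-2 rose by 2.07 ± 0.48 (adjusted p = 0.00381), and that of prdx-2, a peroxiredoxin gene, by 2.19 ± 0.61 (adjusted p = 0.0102). The largest called rises were upstream of the ribosomal protein genes rpl-3 at 2.71 ± 0.66 (adjusted p = 0.00498) and rps-20 at 2.56 ± 0.53 (adjusted p = 0.00284). The region that was lower lay upstream of mir-358 at −1.45 ± 0.58 (adjusted p = 0.0438), from 12 reads against 16. This call was lost in DESeq2, in limma, with 1 read per position and strand, without the read shift, with 500 bp regions and without any single library other than Pol II ChIP 1.

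At sod-3 the authors' peak found in both GFP ChIP libraries covered X 17092182 to 17092693, from 997 to 486 bp upstream of the matched start at X 17093179. In the window from X 17092001 to 17092500, TMM-scaled CPM values (reads of each 500 bp window scaled to a common library size) were 42.4 and 36.3 in GFP ChIP, 7.34 and 6.94 in Pol II ChIP and 7.98 and 9.28 in Input. A shorter sod-3 upstream region of 500 bp left most of this peak out, and its log2 fold change over Input was −0.58. At sod-2 the shared peak ran from 505 bp upstream of the matched start to 21 bp past it, and at ftn-1, which encodes a ferritin, it lay 768 to 283 bp upstream.

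**Figure D1:**
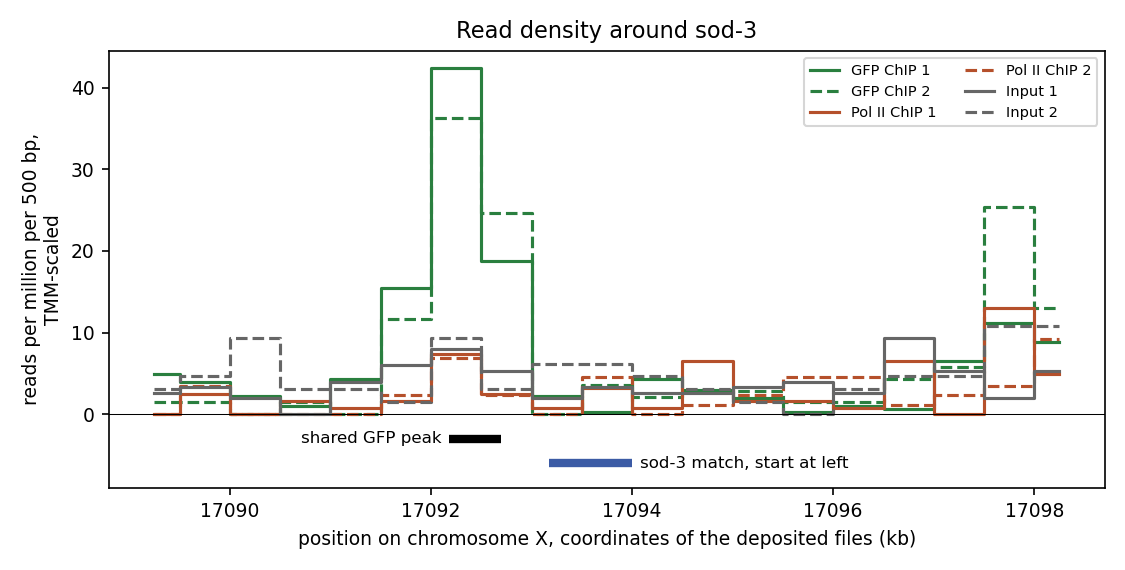
TMM-scaled CPM per 500 bp window across the sod-3 region of chromosome X, with 1 line per library and bars for the authors' shared GFP peak and the sod-3 match. In the window from X 17092001 the GFP ChIP libraries reached 42.4 and 36.3, while the Pol II ChIP and Input libraries stayed between 6.94 and 9.28.

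Of all 97 upstream regions 40 were higher, and of the 62 microRNA loci among them 18, so protein-coding regions were called more often. The kinds of start are unlike. A microRNA start is the first base of the mature sequence, while a protein start needed a match that began within the first 35 residues. Places rich in ChIP reads were easier to rebuild, so the contrast may partly reflect how loci were placed, which was not tested. Shares of the protein-coding lists are to be read against this, and that of the DAF-16 targets does not stand out. Grouped by lists, 3 of the 6 located DAF-16 targets reported to rise with its activity were higher in GFP ChIP over Input (4 when adjusted over the list alone). Beside sod-3 these were ftn-1 at 1.70 ± 0.48 and the small heat shock gene hsp-16.41 at 2.18 ± 0.82. Their neighbour hsp-16.2, transcribed away from hsp-16.41 and sharing its upstream reads, stood at 2.07 ± 0.89 (adjusted p = 0.0565), the glyceraldehyde-3-phosphate dehydrogenase genes gpd-2 and gpd-3 at 1.34 ± 0.85 and the metallothionein gene mtl-1 at 0.78 ± 0.50 (adjusted p = 0.173). Of 8 placed insulin/IGF-1 genes 3 had a located start, and these 3 rose (3 adjusted over the list alone). They were the 14-3-3 protein genes ftt-2 (2.09 ± 0.67) and par-5 (1.93 ± 0.57) and the lipid phosphatase gene daf-18 (1.38 ± 0.49). Among detoxification genes 3 of 5 rose (3 adjusted over the list alone), namely prdx-2, sod-3 and sod-2, while the metallothionein gene mtl-2 stood at −0.37 ± 0.51. Ribosomal protein genes gave 13 of 18 higher (17 adjusted over the list alone), and rpl-32 at 1.00 ± 0.44 and rps-15A at 0.93 ± 0.47 were among those that did not pass.

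Of the chaperone genes, hsp-90 rose by 1.80 ± 0.68 and the constitutive HSP70 gene hsp-1 stood at 1.84 ± 0.78, so that 1 of 2 passed (2 adjusted over the list alone). The autophagy gene lgg-1, at 1.94 ± 0.98 (adjusted p = 0.0946), did not pass in edgeR or limma but did in DESeq2. Neither of the muscle genes passed, act-4 at 1.55 ± 0.73 and unc-54 at 1.29 ± 0.55, which gave 0 of 2 in edgeR, DESeq2 and limma (2 adjusted over the list alone, and 2 at an unadjusted p under 0.05). Of 62 microRNA loci, 18 were higher and 1 lower (16 and 0 adjusted over the list alone). The largest rises were at mir-253 (2.48 ± 0.54), mir-80 (2.47 ± 0.97) and the cluster of mir-229, mir-64, mir-65 and mir-66 (2.45 ± 0.85). The let-7 region, which encodes a developmental timing microRNA, rose by 1.46 ± 0.51 and that of its relative mir-48 by 1.98 ± 0.50, while lin-4 stood at 1.30 ± 0.57 (adjusted p = 0.0609) and mir-52 at 2.57 ± 1.40 (adjusted p = 0.118). In limma's camera test of the 5 lists with at least 3 located members, ribosomal protein genes lay above the other regions (adjusted p = 0.00656) and microRNA loci below them (adjusted p = 0.000113). Since 62 of the 97 regions were microRNA loci, both calls may reflect 1 contrast, protein-coding regions against microRNA loci. The starts of these kinds of locus were placed in unlike ways. Both calls were lost with an estimated correlation (adjusted p = 0.367 for each), and without GFP ChIP 1 the ribosomal call was lost with the preset one (adjusted p = 0.0766). The DAF-16 target, insulin and detoxification lists gave adjusted p = 0.228, 0.245 and 0.516.

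All 41 called regions had the same sign in both same-numbered pairs of libraries. With 2 libraries per group a call nearly requires this, so here and in the comparisons below it adds no separate support. A replicate block raised the counts to 62 higher and 1 lower and a flow cell block to 54 and 1, each including all 40. The counts fell to 5 higher without GFP ChIP 2, to 10 without Input 2 and to 0 without Input 1, where 23 regions had an unadjusted p under 0.05, and to 22 with 500 bp regions. Size factors set on these loci themselves moved the median log2 from 1.30 to 0.07 and gave 1 higher and 14 lower; this centring puts lists with a lower median, such as the microRNA loci (0.90 to −0.38), below 0 by construction.

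**Figure D2:**
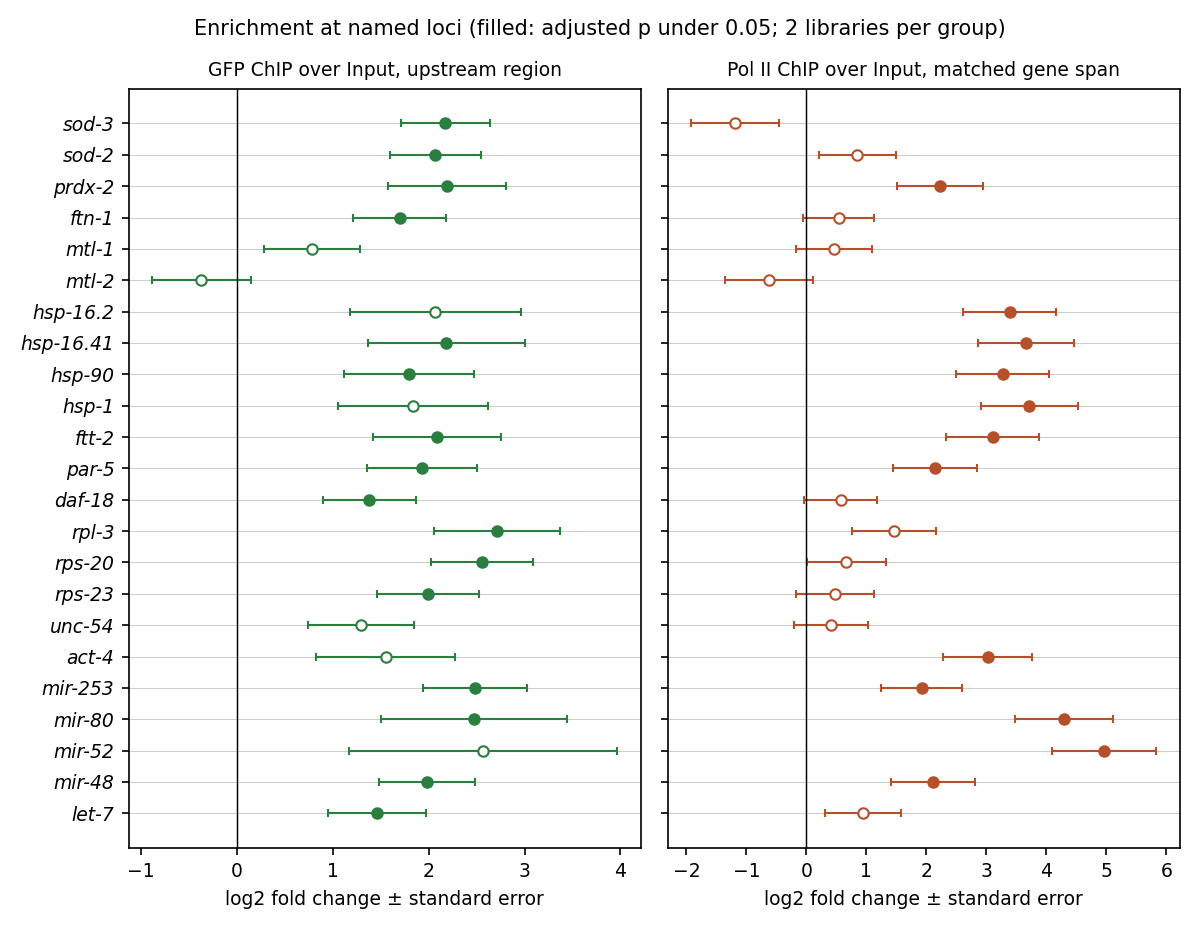
Log2 fold change ± standard error at named loci, for GFP ChIP over Input in upstream regions (left) and Pol II ChIP over Input over matched gene spans (right), with filled points at an adjusted p under 0.05 and 2 libraries per group. The sod-3 point lies at 2.17 in the left panel and at −1.19 in the right panel.

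Pol II ChIP over Input asks which of the located genes carried RNA polymerase II. Over 108 matched gene spans, 46 were higher in Pol II ChIP and 1 was lower. The highest was mir-52 at 4.96 ± 0.87 (adjusted p = 3.03e-06), from 595 and 351 reads against 7 and 17 in Input, followed by mir-80 at 4.29 ± 0.82 (adjusted p = 1.85e-05). Among protein-coding genes hsp-1 rose by 3.72 ± 0.81 (adjusted p = 0.00011), hsp-16.41 by 3.66 ± 0.79, hsp-16.2 by 3.39 ± 0.77, gpd-2 and gpd-3 by 3.29 ± 0.79 and hsp-90 by 3.27 ± 0.77. The sod-3 span stood at −1.19 ± 0.73 (adjusted p = 0.174) and that of daf-16 at 0.34 ± 0.73 (adjusted p = 0.715). At mir-254, the region that was lower, Pol II ChIP had 0 reads against 7 in Input, at least 2.27-fold lower against a floor of 3 reads over the group.

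By list, 3 of 6 located DAF-16 targets were higher in Pol II ChIP than in Input (3 adjusted over the list alone), beside 46 of all 108 spans. The mtl-1 span stood at 0.46 ± 0.63. Of 8 insulin/IGF-1 genes 3 rose (3 adjusted over the list alone): ftt-2 by 3.10 ± 0.77, par-5 by 2.14 ± 0.70 and the kinase gene akt-1 by 2.00 ± 0.69; the phosphoinositide 3-kinase gene age-1 stood at −0.66 ± 0.61. The chaperone genes hsp-1 and hsp-90 rose and hsf-1, the heat shock factor gene, did not pass at 1.04 (2 of 3, and 2 adjusted over the list alone). Detoxification genes gave 2 of 6 (2 adjusted over the list alone), namely prdx-2 at 2.23 ± 0.71 and the copper/zinc superoxide dismutase gene sod-1 at 1.83 ± 0.67. The single located autophagy and lipid genes, lgg-1 at 3.03 ± 0.75 and the fatty acid desaturase gene fat-6 at 1.86 ± 0.66, both passed, also when adjusted over the list alone (1 of 1 each). Of the ribosomal protein genes 5 of 18 rose (0 adjusted over the list alone; 9 had an unadjusted p under 0.05 in edgeR, and DESeq2 called 4 and limma 6), led by rps-16 at 1.97 ± 0.67, while rps-20 stood at 0.66 ± 0.66.

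The muscle gene act-4 rose by 3.02 ± 0.74 and unc-54, the body-wall myosin gene, stood at 0.41 ± 0.62 (1 of 2, and 1 adjusted over the list alone). The neuronal synaptobrevin gene snb-1 rose by 2.27 ± 0.65 and the synaptic vesicle gene rab-3 stood at −0.03 ± 0.65 (1 of 2, and 1 adjusted over the list alone). The intestinal gene mtl-2, at −0.63 ± 0.73, did not pass (0 of 1 in edgeR, DESeq2 and limma, and at an unadjusted p under 0.05). MicroRNA loci gave 27 of 62 higher and 1 lower (27 and 1 adjusted over the list alone), with the cluster of mir-56, mir-55 and mir-54 at 3.94 ± 0.82, mir-79 at 3.81 ± 0.76 and mir-58.1 at 3.46 ± 0.74.

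All 47 called spans had the same sign in both same-numbered pairs, but with the flow cell as a block only mir-52, mir-80, hsp-1, hsp-90 and the cluster of mir-56, mir-55 and mir-54 were called (5 higher, 0 lower, with 41 spans at an unadjusted p under 0.05). The median log2 of all spans was then 1.18 against 1.40 without the block, and both Pol II ChIP libraries came from one flow cell, with Input 2 as the only Input library there. A replicate block gave 48 higher, 42 of them among the 46, and 1 lower. The count of 46 fell to 26 without Input 2 and to 0 without Input 1 (27 at an unadjusted p under 0.05). It fell to 5 higher and 2 lower with size factors set on these loci, a centring that moved the median log2 from 1.40 to −0.07 and by construction put lists with a median near or below 1.40 under 0. With only the first 500 bp of the 54 spans where these could be taken, edgeR called 0 of either sign (13 at an unadjusted p under 0.05).

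Set directly against each other, GFP ChIP and Pol II ChIP differed at 11 of the 97 upstream regions, 5 higher in GFP ChIP and 6 lower. The largest difference was at sod-3, where GFP ChIP exceeded Pol II ChIP by 2.73 ± 0.48 (adjusted p = 0.000419), and sod-2 followed among protein-coding genes at 1.48 ± 0.45 (adjusted p = 0.034). The microRNA loci mir-355 (1.96 ± 0.47), mir-249 (1.84 ± 0.55) and mir-237 (1.77 ± 0.49) were also higher in GFP ChIP than in Pol II ChIP. At mir-249 GFP ChIP lay near Input, so this difference does not show enrichment in GFP ChIP. There Pol II ChIP, at TMM-scaled CPM of 8.97 and 1.16, lay below Input at 19.95 and 20.11. At sod-3, sod-2, mir-355 and mir-237 GFP ChIP lay above Input in each same-numbered pair. Lower in GFP ChIP were mir-124, a neuronal microRNA (−1.99 ± 0.47, adjusted p = 0.00918), mir-358 (−1.89 ± 0.55), mir-87 (−1.75 ± 0.55), mir-62 (−1.73 ± 0.54), mir-72 (−1.72 ± 0.56) and mir-50 (−1.51 ± 0.47). By list, 1 of 6 DAF-16 targets was higher (1 adjusted over the list alone), 2 of 5 detoxification genes (2 adjusted over the list alone) and 3 of 62 microRNA loci with 6 lower (4 and 7 adjusted over the list alone).

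The other lists gave 0 called upstream regions in this direct comparison by edgeR: ribosomal protein genes (rpl-32 at 0.99 ± 0.44, rpl-3 at 0.40 ± 0.59), insulin/IGF-1 genes (daf-18 at 0.67 ± 0.46), chaperone genes (hsp-90 at −0.98 ± 0.63), lgg-1 (−1.47 ± 0.93), muscle genes (act-4 at −0.86 ± 0.68) and mtl-2. DESeq2 and limma also called 0 in these lists, and 1 ribosomal region had an unadjusted p under 0.05 against 0 in the others. All 11 calls had the same sign in both same-numbered pairs. A replicate block gave 10 higher and 16 lower, whereas with the flow cell as a block 2 calls, sod-3 at 2.79 and mir-355 at 2.09, and 0 lower remained. The counts were 2 higher and 0 lower without GFP ChIP 1, 5 and 5 without GFP ChIP 2, 3 and 0 without either Input library, and 0 and 0 without either Pol II ChIP library (21 and 18 at an unadjusted p under 0.05) or with 500 bp regions (17 at an unadjusted p under 0.05). Scaling by total reads gave 3 and 1, size factors 8 and 8, DESeq2 4 and 2 and limma 5 and 3.

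Across the whole genome, 6158 of 147829 tested 500 bp windows were higher in GFP ChIP than in Input and 771 lower, with a median log2 fold change of 2.44 among the higher ones. Joined over gaps of up to 500 bp, the higher windows made 4967 runs. Nearly all runs with the largest mean fold were single windows with 0 Input reads, such as X 2011001 to 2011500 with 41 GFP ChIP reads (adjusted p = 0.0132; at least 6.65-fold higher against a floor of 3 reads over the group). At X 12247001 to 12247500, 80 reads stood against 1 in Input, a ratio of 38.9 (95% counting interval 6.79 to 1556). Here and for the windows named below, a choice by the largest fold favours windows with few reads in the group compared against. The floors and intervals do not allow for this choice, so the true folds may be lower. The longest runs, chosen after their values were seen, were IV 14609501 to 14614500 with 7 windows at a mean log2 of 2.86 (1212 reads against 82) and X 8750501 to 8755000 with 7 windows at 2.48 (998 against 90). Of tested windows, 5.81% were higher on chromosome X and between 3.30% and 4.22% on each autosome.

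For these GFP ChIP windows a replicate block gave 10285 higher and 1477 lower and a flow cell block 9893 and 1908. Counts were 515 higher and 2 lower without GFP ChIP 1, 0 and 0 without GFP ChIP 2 (22497 at an unadjusted p under 0.05), 96 and 70 without Input 1 and 4413 and 452 without Input 2. Scaling by total reads, which moved the median log2 of all windows from −0.26 to −0.51, gave 3604 and 1076, 1 kb windows gave 6062 and 2540, and DESeq2 gave 7038 and 37.

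Pol II ChIP was higher than Input in 2382 windows, with a median log2 of 2.87, and lower in 137, and the higher windows made 1442 runs. By mean fold the first run was V 20242501 to 20243000, with 29 reads against 0 in Input (at least 9.94-fold higher), and at II 4551501 to 4552000 51 reads stood against 1, a ratio of 52.5 (95% counting interval 9.001 to 2112). The longest runs, chosen after their values were seen, were II 10541501 to 10551000 with 17 windows at a mean log2 of 3.25, V 6221001 to 6228500 with 15 windows at 3.26, and X 16929501 to 16935500 with 11 windows at 4.23 (3930 reads against 176). The run X 3112001 to 3116500, with 9 windows at 3.42, covered gpd-2 and gpd-3. The share of windows higher in Pol II ChIP was 1.06% on X, the lowest of the chromosomes, and reached 2.26% on chromosome III.

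The Pol II ChIP window counts were 5083 higher and 383 lower with a replicate block and 1647 and 70 with a flow cell block. They were 1072 and 83 without GFP ChIP 1, 868 and 62 without GFP ChIP 2, 2781 and 3 without Pol II ChIP 1, 460 and 1 without Pol II ChIP 2, 48 and 1 without Input 1 and 3513 and 423 without Input 2. They were 1144 and 157 when scaled by total reads, which moved the median log2 from −0.01 to −0.30, 3229 and 11 in DESeq2, 3994 and 314 in limma and 2746 and 414 in 1 kb windows.

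Between the precipitations, 1328 windows were higher in GFP ChIP and 3659 in Pol II ChIP. By mean fold the first was III 8480001 to 8480500, with 56 GFP ChIP reads against 0 in Pol II ChIP (at least 8.83-fold higher). The longest runs higher in GFP ChIP, chosen after their values were seen, were X 8969501 to 8972000 with 4 windows at a mean log2 of 2.96 (430 reads against 30) and X 17091501 to 17093000, upstream of sod-3, with 3 windows at 2.78 (333 reads against 24). DESeq2 called 193 and 742, limma 1217 and 2199, and edgeR 2031 and 3820 when scaled by total reads and 2230 and 5054 in 1 kb windows. A replicate block gave 3277 higher and 5719 lower and a flow cell block 929 and 1472, and size factors moved the split to 3056 and 2744 and the median log2 from −0.12 to 0.07. Counts were 0 and 0 without GFP ChIP 1 (18260 at an unadjusted p under 0.05) and 12 and 47 without GFP ChIP 2. They were 277 and 2781 without Pol II ChIP 1, 0 and 31 without Pol II ChIP 2 (22843 at an unadjusted p under 0.05), 2948 and 6354 without Input 1 and 2971 and 6097 without Input 2.

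The enrichments of GFP ChIP and Pol II ChIP were compared over the same Input libraries. Of the windows higher than Input, 558 were called for both precipitations. Independent lists would give 99.2, a value that leaves out the shared Input libraries, and 3 simulations of unchanged groups gave 0, a value that leaves out real enrichment, so neither gives the overlap to be had from shared Input libraries alone. Across windows the log2 enrichments correlated at a Spearman coefficient of 0.48, below the 0.53 of the simulation, with a covariance of 0.763 against a simulated 0.476. Across the 97 upstream regions the coefficient was 0.593, within the range of 50 simulations (mean 0.492, highest 0.653), with a covariance of 0.674 against 0.190. With a different Input library for each precipitation it was 0.547 or 0.308, depending on the assignment. Regions are not independent replicates, only 1 Input library remained in each part of the split, and part of these values may come from the shared Input libraries.

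The authors' peak lists held 14260 and 8345 regions for GFP ChIP and 4997 and 2541 for Pol II ChIP, called in each library alone. Of the peaks in the smaller GFP ChIP list, 89.1% (7432 of 8345) overlapped a peak of the other by at least 1 bp, against a mean of 12.1% and a highest value of 13.9% in 100 shifts of one list along the chromosomes. For Pol II ChIP the share was 63.1% (1604 of 2541), against 5.77% and 7.60%. Of 7218 regions shared by both GFP ChIP lists, 1159 overlapped a region shared by both Pol II ChIP lists, against 2.82% and 3.39%. Each permutation p was 0.0099 (one-sided), the smallest that 100 shifts can give. Shifting also breaks what lists may have in common without binding, such as the Input used and the places where reads match singly. The overlap of GFP ChIP and Pol II ChIP peaks therefore does not by itself show shared binding.

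Peaks lay upstream of many located genes. A GFP ChIP peak shared by both libraries overlapped 54 of the 97 upstream regions (11.8 on average when shifted, 23 at most) and a shared Pol II ChIP peak 36 (3.56 and 8), and 28 had both. The loci were placed on sequence rebuilt from ChIP and Input reads alike, so places rich in ChIP reads were easier to place. Shifted positions are therefore not a matched comparison, and the excess over them was not tested. These GFP ChIP peaks lay upstream of 30 of 35 protein-coding genes and 24 of 62 microRNA loci. Among the peaks ranked highest by the authors' q-value in both libraries, the authors' ratios of GFP ChIP to normalised Input were 3.87 and 6.25 at II 10546556 to 10554319, 5.05 and 9.90 at II 11618274 to 11621036 and 7.83 and 8.67 at II 5543205 to 5544481. The first 10 lay on chromosomes I and II and all overlapped shared Pol II ChIP peaks. On the other chromosomes the first 10 included III 9050928 to 9054379 (2.47 and 2.43) and IV 14032571 to 14034756 over mir-52 (2.11 and 3.83). For Pol II ChIP the highest ranks were at X 16929267 to 16932694 (11.8 and 6.13), II 10541819 to 10554293 (8.48 and 5.44) and, on chromosome IV, 17278035 to 17282016 over hsp-1 (9.20 and 3.13).

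**Figure D3:**
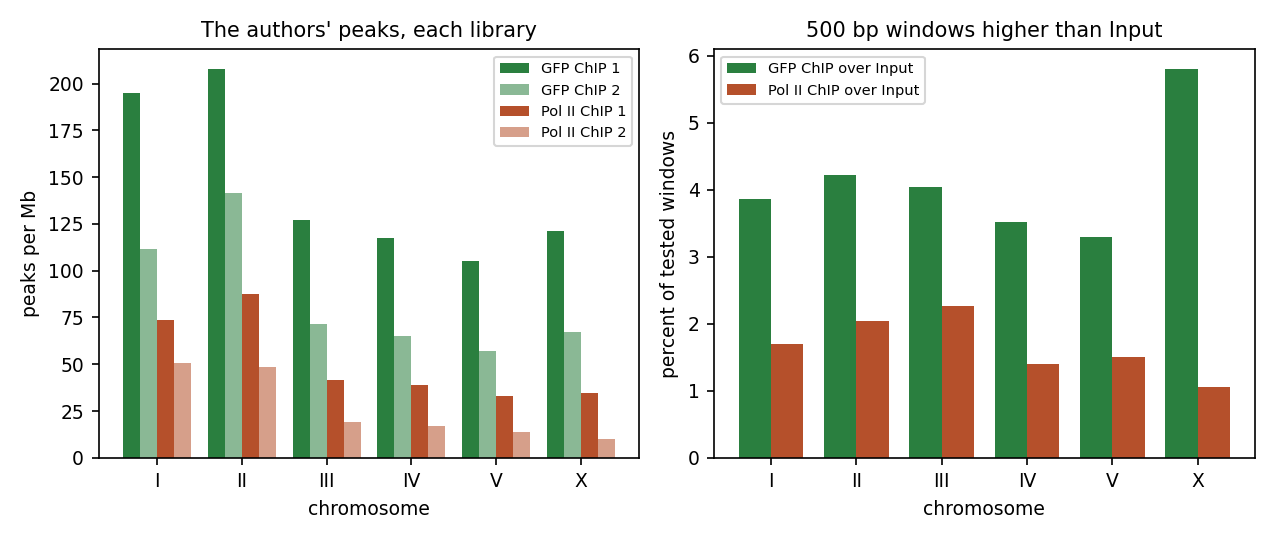
Left, the authors' peaks per megabase on each chromosome, 1 bar per library; right, percent of tested 500 bp windows higher than Input on each chromosome for GFP ChIP and Pol II ChIP. Peaks were densest on chromosomes I and II in all 4 lists, while windows higher in GFP ChIP were most frequent on X at 5.81%.

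The shared GFP ChIP peaks, which covered 4.18% of the genome, held 26.8% and 33.3% of the GFP ChIP reads (30.0% ± 4.59, SD, n = 2), 18.9% ± 0.467 of the Pol II ChIP reads and 7.46% ± 2.01 of the Input reads. The shared Pol II ChIP peaks, covering 1.68%, held 13.8% ± 2.66 of the Pol II ChIP reads, 8.44% ± 2.15 of the GFP ChIP reads and 2.96% ± 1.15 of the Input reads. These shares are given as values without a test; a permutation test of 2 libraries against 2 cannot reach a p under 0.05.

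The forkhead core sequence GTAAACA, bound by DAF-16, was found within 100 bp of the centre of 116 of 2070 shared GFP ChIP peaks with enough rebuilt sequence (5.60%, 95% Wilson interval 4.69 to 6.68) and in 150 of 4140 flanks 1 kb away (3.62%, 3.10 to 4.24). The odds ratio was 1.58 (Fisher's exact test, two-sided, p = 0.000406). In shared Pol II ChIP peaks it was found in 14 of 650 centres and 37 of 1300 flanks (odds ratio 0.751, p = 0.452 in Fisher's exact test), and the difference between the antibodies was not tested. By the same exact test the GFP ChIP odds ratio was 1.53 within 250 bp (p = 8.64e-06) and 1.53 for the longer TTGTTTAC (p = 0.0259). The exact test lost its call in the better-ranked 3471 shared peaks (odds ratio 1.29, p = 0.164), on chromosomes III, IV, V and X alone (1.41, p = 0.0575) and in the 1000 peaks of highest recomputed enrichment (1.35, p = 0.519).

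The transgene was looked for in the Input libraries. Over the daf-16 match, I 10764380 to 10773089, Input read density was 3.07 and 2.63 times the median of 12 other located genes (mean 2.85 ± 0.306, SD, n = 2), whereas the highest of those genes reached 1.89 (hsp-1) and 2.03 (ftt-2). The excess lay at the ends of the match: the windows at I 10764001, 10772501 and 10773001 held 84, 84 and 217 reads in Input 1 and 58, 34 and 120 in Input 2. From I 10765501 to 10772500, most of the match, windows held 3 to 16 and 2 to 11 reads, against medians of 7 and 3 over all tested windows. The ratio over the whole match was 2.43 and 2.53 in GFP ChIP and 1.66 and 1.30 in Pol II ChIP. Around the match, windows over 5 times the genome median in Input ran from I 10756501 to 10775500, where 24 windows had a median of 47.6 times. The rol-6 marker gene, which the strain is known to carry, could not be placed here by its own sequence. Windows at II 8731001 to 8735500, with 9 windows at a median of 82.4 times, lay between mir-85 and rpl-32, an interval that holds rol-6 and 244 genes in all in the gene order of the WBcel235 assembly, so it does not single out rol-6.

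**Figure D4:**
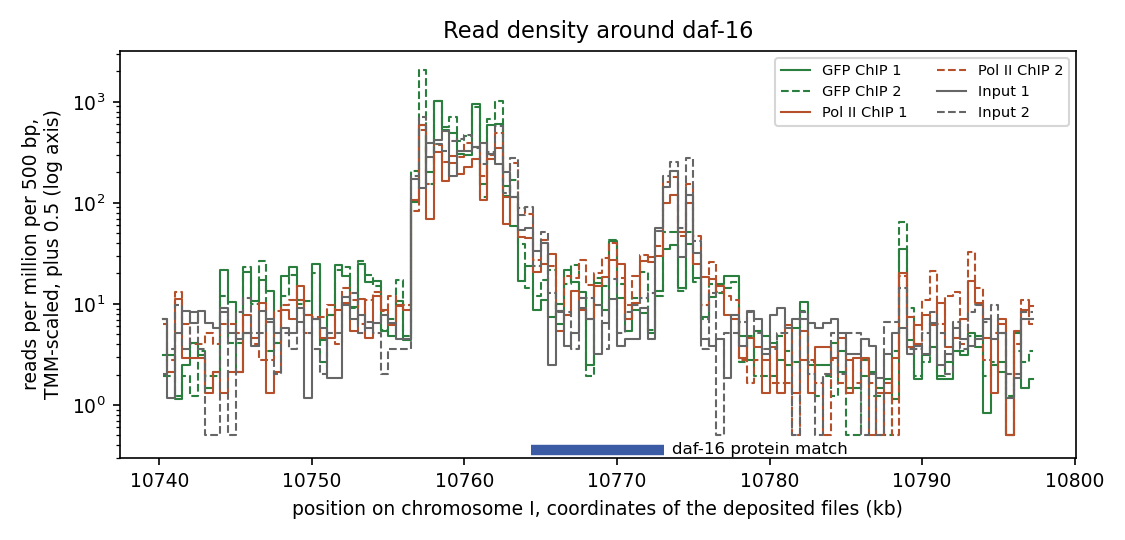
CPM per 500 bp window (TMM-scaled, plus 0.5, log axis) across the daf-16 region of chromosome I, 1 line per library, with a bar for the daf-16 protein match at I 10764380 to 10773089. All 6 libraries rose on both sides of the match, within I 10756501 to 10775500.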

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

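In this part the tests of the authors' Input scaling, of window shares, of GC content and of sampling noise were chosen after the result they bear on was seen; those of shared peak strength (reworded later, with its bounds kept), duplicate reads, reads outside peaks and read number were set before. No biological explanation was tested for chromosome X or the Input libraries.

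The authors' peaks were denser on chromosomes I and II than on the others, by ratios of 1.73 and 1.96 in the GFP ChIP lists and 2.20 and 3.36 in the Pol II ChIP lists. For more binding there, the share of windows higher than Input gave no decision by the bounds set. For GFP ChIP the ratio between I and II and the other chromosomes was 0.959, but 1.13 against III, IV and V alone, past the bound of 1.1. For Pol II ChIP it was 1.25 and 1.12. These ratios lay below the peak density ratios of the same precipitation, so a difference of that size was not seen in windows. With 1 Input scale for all chromosomes shared GFP ChIP peaks on I and II gave a log2 difference of −0.27. This was just short of the difference of 0.3 at which more binding would have been set aside. It cannot weigh binding, because the peaks compared were those that the authors' lists let through. Of shared GFP ChIP peaks, 3.22% were under 2-fold on I and II and 0.0261% elsewhere. More binding of a smaller size cannot be told apart from other causes. A candidate explanation is the authors' Input scaling: their normalised Input per Input read inside peaks on I and II was at most 0.583 of that elsewhere in the 4 lists, which would raise their ratios there. Which Input library and which scaling unit the authors used stays open.

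GFP ChIP reads were 1.45 and 1.46 times as dense on chromosome X as on the autosomes, and 1.32 and 1.35 times after division by the same-numbered Input, while the Pol II ChIP values were 0.959 and 0.973. GC content as the whole cause is argued against, since within each of 4 groups of 10 kb bins by GC content the log2 difference between X and autosomes was at least 0.45. Duplicate reads are argued against by a ratio of at least 1.32 with 1 read per position and strand, and reads inside peaks alone by a ratio of at least 1.496 outside all peaks. An antibody or fusion protein property that acts along the whole chromosome may remain, which these libraries without an untagged strain leave open.

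The Input libraries were uncorrelated across 500 bp windows (r = 0.0206 on log2 CPM with 1 read added, 0.0243 with the prior count of 2 used elsewhere), although both are unprecipitated DNA of the same strain. Sampling noise around a single profile, as the whole cause, is argued against. In 10 kb bins 26.1% differed past the limit of a chi-square test that chance would pass in 5%. Read density per rebuilt base correlated there with GC content at −0.541 in Input 1 and 0.571 in Input 2. Counting noise around a single profile would not give opposite trends. The test sets 2 single libraries against counting noise, so it does not show why they differ, and across these bins they still correlated at 0.507. Read number gave no decision: libraries drawn from the sum of both Input libraries correlated at 0.412, above the bound of 0.2 set for setting it aside, but the same draws from the sum of libraries simulated on an even profile gave 0.306, so the test could hardly have come out low. Read number per window correlated with GC content at −0.285 in Input 1 and 0.356 in Input 2. Removal of these trends raised the correlation of 500 bp windows from 0.0175 to 0.122, by 0.105, near the lower of the bounds of 0.1 and 0.2. Per rebuilt base it rose from −0.0578 to 0.0567, and the rises were 0.0890 and 0.0978 without windows over 4 times the median. The bounds were first set for 10 kb bins, where the correlation rose from 0.507 to 0.711, by 0.204 and past 0.2. Per rebuilt base it rose there from −0.185 to 0.169. The move to 500 bp windows came after the 10 kb values were seen, so the 2 scales give no single decision on GC content. Sequence errors differed too: 34.8% of uniquely matching reads had 0 errors in Input 1 and 88.4% in Input 2. Matches with 2 errors made up 30.2% and 3.56%, and the part of these errors was not tested. Reads per window were few, and each flow cell gave 1 Input library, with different read lengths. The parts of read number, GC content and sequence errors therefore cannot be told apart.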

How the results depend on the processing

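The flow cell block, the peak sets limited to chromosomes III, IV, V and X or to the 1000 most enriched peaks, and the settings of the GFP ChIP gene spans were chosen after the results were seen. Except where a setting's own construction is named, the cause was not tested. Depth limits all comparisons with Input (a median of 7 and 3 reads per window), and where a library is left out its lone partner is assumed to vary like the other groups.

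For windows, the counts higher in GFP ChIP than in Input, in Pol II ChIP than in Input and in GFP ChIP than in Pol II ChIP were 3604, 1144 and 2031 when scaled by total reads. A replicate block, used because the numbers were treated as a pairing, gave 10285, 5083 and 3277 (1477, 383 and 5719 lower). The flow cell block gave 9893 higher and 1908 lower for GFP ChIP over Input, 70 lower for Pol II ChIP over Input and 1472 lower in the direct comparison. Size factors gave 3056 higher in the direct comparison, and 1 kb windows 2230 there, with 2540 and 414 lower than Input for GFP and Pol II ChIP. DESeq2 called 37, 11 and 742 lower and 193 higher in the direct comparison, limma 3994 higher and 314 lower for Pol II ChIP and 2199 lower in the direct comparison, and with no filter, which tests more windows, 1401 and 342 were lower than Input. The run at I 7462501 to 7463000 turned to −0.050 in 1 kb windows, which add neighbouring reads.

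For upstream regions in GFP ChIP over Input, size factors gave 1 higher and 14 lower, a replicate block on the pairing 62 higher, and 500 bp regions 22 higher; 0 were lower with 500 bp regions, 1 read per position, DESeq2, limma or no shift. The sod-3 region turned to −0.58 with 500 bp, which leaves out most of its peak. For Pol II ChIP gene spans, size factors gave 5 higher and 2 lower, the flow cell block 5 and 0 and the first 500 bp 0 and 0, with 0 lower for 1 read per position and DESeq2. For GFP ChIP over Pol II ChIP the higher and lower counts were 3 and 1 (total reads), 8 higher (size factors), 10 and 16 (replicate block on the pairing), 2 and 0 (flow cell), 2 and 1 (no shift) and 0 and 0 (500 bp), and 2, 2 and 3 were lower with 1 read per position, DESeq2 and limma. With an estimated correlation camera called 0 lists in GFP ChIP upstream regions. The replicate block on the pairing changed no call of the gene lists by camera.

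Without each library in turn the higher counts ranged from 0 to 9002 (GFP ChIP windows), 48 to 3513 (Pol II ChIP windows), 0 to 2971 (direct windows), 0 to 48 (GFP ChIP upstream regions), 0 to 56 (Pol II ChIP spans) and 0 to 5 (direct upstream regions), and the lower counts from 0 to 840, 1 to 423, 0 to 6354, 0 to 1, 0 to 1 and 0 to 5. Camera called 1 to 2 lists in GFP ChIP upstream regions and 0 to 0 in Pol II ChIP spans.

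With the better-ranked peaks, which cover less sequence, shared GFP ChIP peaks held 19.2% of GFP ChIP, 12.61% of Pol II ChIP and 4.48% of Input reads, and shared Pol II ChIP peaks 6.06% of GFP ChIP and 10.9% of Pol II ChIP reads. The GTAAACA odds ratio lost its call at 1.29 (better-ranked peaks), 1.41 (chromosomes III, IV, V and X) and 1.35 (1000 most enriched). Each set had fewer peaks and also a lower share of centres with GTAAACA (4.93%, 5.15% and 4.22% against 5.60%). Density over daf-16 in Input was 2.45 times with 1 read per position, and the correlation of GFP ChIP and Pol II ChIP upstream enrichments was 0.547 or 0.308 with separate Input libraries, depending on the assignment. Of single named upstream regions in GFP ChIP over Input, 284 values under other settings stayed on their side of the threshold, 45 lost a call, 20 gained one and 1 reversed; for Pol II ChIP spans 290 stayed, 58 lost and 2 gained a call, and in the direct comparison 229, 49 and 2. With 1 library left out, 137 values stayed, 68 lost and 5 gained a call in GFP ChIP upstream regions, 181 stayed and 41 lost one in Pol II ChIP spans, and 49 lost one and the rest stayed in the direct comparison.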

Other observations

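The comparison of GFP ChIP with Input over matched gene spans, the short sequences, the high-copy regions and the GFP reads were all looked at after the other results were seen. Over gene spans, 9 of 108 loci were higher in GFP ChIP than in Input and 0 lower. These were the microRNA loci mir-73 with mir-74 (2.71 ± 0.72, adjusted p = 0.0188 in edgeR), mir-79 (2.71 ± 0.76), mir-80 (2.55 ± 0.80), mir-53 (2.51 ± 0.74), mir-48 (2.41 ± 0.69), mir-52 (2.33 ± 0.81), mir-75 (2.12 ± 0.68) and mir-355 (1.92 ± 0.62), and the small heat shock gene hsp-16.2 (2.28 ± 0.75, adjusted p = 0.0348). The sod-3 span, with its peak upstream, stood at −0.98 ± 0.65 and that of daf-16 at −0.51 ± 0.73. Spans at microRNAs include 250 bp on each side, so they overlap their upstream regions. DESeq2 called 6 and limma 12. The count was 0 with 1 read per position and strand, with the flow cell as a block and with size factors, where 23, 23 and 22 spans had an unadjusted p under 0.05, and 5 when scaled by total reads. It was 1 without GFP ChIP 1, 18 and 20 without Pol II ChIP 1 and 2, and 0 without GFP ChIP 2, Input 1 or Input 2 (10, 14 and 23 at an unadjusted p under 0.05).

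Among 8192 sequences of 7 bases, GTAAACA ranked 212 by a z-score, the log ratio of its frequency in the centres of shared GFP ChIP peaks over flanks divided by its counting error (ratio 1.56), and ranked 3 of 210 among sequences of the same base content. In shared Pol II ChIP peaks it ranked 6058, and 114 of 210. Simple repeats had higher ratios in both: in GFP ChIP peaks CACACAC reached 2.89 and ACACACA 2.70, and in Pol II ChIP peaks 2.84 and 2.56.

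Reads that matched a GFP coding sequence, written down from general knowledge, exactly over 27 bases numbered 517 and 487 in GFP ChIP, 327 and 194 in Pol II ChIP and 165 and 235 in Input, and 0 for the reversed sequence. Their density was 48.4, 55.2, 45.9, 34.9, 52.7 and 66.7 times the nuclear mean. Each library covered between 90.9% and 93.4% of the 717 bases.

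High Input density was found in few places. In Input 1 and Input 2 the 10 kb bin at I 10750001, beside daf-16, lay at 25.6 and 32.6 times the median and in GFP ChIP at 43.1 and 67.6 times. The bin at II 8730001 lay at 33.6 and 33.8 times, and that at the right end of chromosome I, I 15060001, past unc-54, at 42.0 and 87.6 times.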
